A study of Physcomitrium patens with 6 samples.

How the data were processed

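Messenger RNA was sequenced from protonema of the moss Physcomitrium patens (formerly Physcomitrella patens) after treatment with abscisic acid (ABA), a plant hormone of the response to drought and osmotic stress. Protonema is the filamentous juvenile tissue that grows from spores or from regenerating fragments. Per the labels, there were 3 groups (0, 30 and 60 minutes of ABA) of 2 biological replicates each, 6 libraries in all, made with a stranded mRNA kit from Trizol-extracted RNA. The ABA concentration is given as 10 µM in the series design and as 10 mM in the treatment protocol, and this difference could not be resolved from the labels. The treatment protocol states that control cultures received methanol, the carrier; how long before collection the 0 minute cultures received it is not given in the sources used here. A difference between a treated time and 0 minutes therefore cannot be separated from an effect of time in the shaken culture after an addition.

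The authors deposited 1 table per library of whole-number read counts per gene, which were used as raw counts because they are whole and sum to a different total in each library. The submitters' processing notes name cutadapt, TopHat, HTSeq and DESeq2, without versions or roles; the alignment settings, the genome build, the annotation and the strand setting of the count are not given in the sources used here. Each deposited count table holds 32926 gene IDs and 5 summary rows that name no gene. Of these summary rows, reads in no gene took 1.66% to 2.14% of each library's total, and the rows for ambiguous, low-quality, unaligned and not uniquely aligned reads were 0 in every library. The summary rows were left out of library sizes and tests. Of the IDs, 32234 begin with Pp3c and 692 with Pp3s. None of the 32926 IDs matched any identifier among the 27567 genes of the RefSeq table used here (assembly ASM5946719v1), and the count files do not pair IDs with names. Genes are therefore reported by ID and as groups defined by their response, with no names, functions or coordinates. No ID matched, so the 33 gene lists that had been fixed as description patterns, the tissue marker lists among them, and the planned search for ABA-responsive elements upstream of genes were not run.

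Gene counts summed to between 12450250 and 17822775 per library. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 18949 genes holding 99.94% to 99.97% of the gene counts. Counts were scaled by TMM, and each comparison was tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3; estimateDisp, glmQLFit and glmQLFTest) in a model of the 3 groups fitted to all 6 libraries, which leaves 3 residual degrees of freedom per gene before moderation. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, with no fold threshold. The standard error of a log2 fold change was taken as its size divided by the square root of F. CPM values are read counts relative to library size, scaled by TMM. The common dispersion corresponded to a coefficient of variation between replicates of 10.0%. On simulated data drawn from the 0 minute means, the real library sizes and the fitted dispersions, with 200 genes changed that had a mean of at least 20 counts, the test recovered 31.3% of 1.5-fold, 95.5% of 2-fold and 100% of 4-fold changes in the 30 versus 0 minute comparison (18509 genes). In the 60 versus 0 minute comparison (18515 genes) it recovered 20.9%, 83.6% and 100%. Unchanged genes made up 6.2% and 6.8% of the calls, respectively. With so few changed genes the adjusted threshold is stricter than in the real comparisons, so these shares do not carry over to them directly. Each gene also had the same dispersion in all simulated groups. The real replicates differed more at 60 than at 30 minutes (chi-square per degree of freedom 16.3 and 3.41), which the simulation did not include.

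Libraries of 1 group correlated across genes with r of 0.986 to 0.993 on the log2 CPM scale, and the replicates of each group differed beyond sampling noise (chi-square per degree of freedom 7.19 at 0, 3.41 at 30 and 16.3 at 60 minutes). Replicate numbers are shared between groups, but the labels do not say that a number marks a shared culture or day, and replicates were not treated as pairs. The labels give no batch or date.

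The 3 comparisons, their overlap, the test, the threshold, the alternatives and the rule for named genes were fixed before the data were examined. The groups of genes by timing, by expression level and by 0 counts, and the shares of gene counts, were chosen after. The rule for named genes takes, in each comparison, the called genes with the largest fold changes among those with a mean CPM of at least 2 and libraries that do not overlap between groups. Its parts that need a description could not be used. Since the IDs have no names, the text gives only the 2 highest and 2 lowest genes of the comparison of 60 with 0 minutes. A fold against a group with 0 counts was computed against a floor of 3 counts per library, also where the comparisons of 30 and 60 with 0 minutes count genes past 2-fold, 8-fold and 32-fold; the fold thresholds among the alternatives and the bars of the plot of calls use fitted folds. A fold against a group with 1 to 5 counts is also given as a ratio of counts with its exact 95% interval from the binomial distribution of the 2 counts. Such intervals and floors cover counting error only, since the labels name no molecular identifiers. Medians over groups of genes use the fitted log2 fold changes, and those of all called genes were equal to 2 decimals with such genes at their bound. The alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), DESeq2 size factors, upper-quartile factors, total counts alone, no filter, a stricter filter (CPM of at least 5 in 2 libraries), a replicate block, 2 fold thresholds, a fit to only the 4 libraries compared, and leaving out each library. After the data were examined, 2 more were added: a fit with 1 gene of each set with nearly the same counts and cyclic loess offsets. A split of genes by their level at 0 minutes was also added. The overlap of the 2 comparisons that share the 0 minute libraries was set beside 20 simulations of unchanged groups, and genes that turned back were set beside 20 simulations in which the 60 minute means equalled the 30 minute means for all genes except those called after 30 minutes that had not turned back. Those simulations called a mean of 5303 genes at 60 versus 30 minutes, against 6813 in the data, so their adjusted threshold was somewhat stricter.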

Results

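Protonema libraries were compared at 0, 30 and 60 minutes of ABA, with 2 biological replicates per time. Gene counts summed to 17822775 and 16407676 at 0 minutes, 17580410 and 12450250 at 30 minutes and 16095741 and 17550096 at 60 minutes. Of 32926 gene IDs, 9334 had no count in any library and 18949 were tested. Libraries separated by time. The first principal component of log2 CPM held 84.6% of the variance and placed the 0 minute libraries at -120.5 and -119.1, the 30 minute libraries at 29.5 and 31.6 and the 60 minute libraries at 84.0 and 94.5. The correlation across genes between libraries of different times ranged from 0.778 to 0.960, below the lowest within a time (0.986).

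The comparison of 30 with 0 minutes asks which transcripts changed soon after ABA was added. Within 30 minutes, 3715 genes rose and 3181 fell, which was 36.4% of the genes tested. At least 8-fold changes were called for 555 genes that rose and 70 that fell, and at least 32-fold changes for 268 and 4 genes. The median log2 fold change was 0.95 among genes that rose and -0.78 among genes that fell. For each of the 6896 called genes, both libraries of one time lay beyond both of the other; 74.2% of all tested genes were separated in this way, against 33.3% for 4 libraries in random order. With 2 libraries per time, leaving out 1 lowered the count to 4394 (0 minutes, replicate 2), 4415 (30 minutes, replicate 1) or 4334 (30 minutes, replicate 2). The balance depended on scaling: risen genes were 53.9% of calls with TMM, 39.0% with total counts alone and 27.7% with upper-quartile factors.

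The comparison of 60 with 0 minutes extends the time course. At 60 minutes 5383 genes rose and 5587 fell, 57.9% of those tested. Changes of at least 2-fold were called for 2469 genes that rose and 2884 that fell, and changes of at least 32-fold for 370 and 23 genes. Genes that rose had a median of 16.4 CPM at 0 minutes, 31.1 at 30 minutes and 40.5 at 60 minutes. Genes that fell had medians of 12.2, 8.49 and 5.35 CPM at those times. Risen genes were 49.1% of calls with TMM, but 21.9% with total counts alone and 26.6% with upper-quartile factors. Those settings shifted the median log2 fold change of all tested genes to -0.50 and -0.39, from -0.04 with TMM, so each gene's change is relative to the scaling chosen. At 30 minutes the shifts were to -0.16 and -0.26, from -0.02. Fits to only the 4 libraries compared called 10164 genes at 60 minutes and 9092 at 30 minutes, against 10970 and 6896 with all 6 libraries. The gap between the times was smaller in those fits, so part of it follows from fitting all 6 libraries together.

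**Figure D1:**
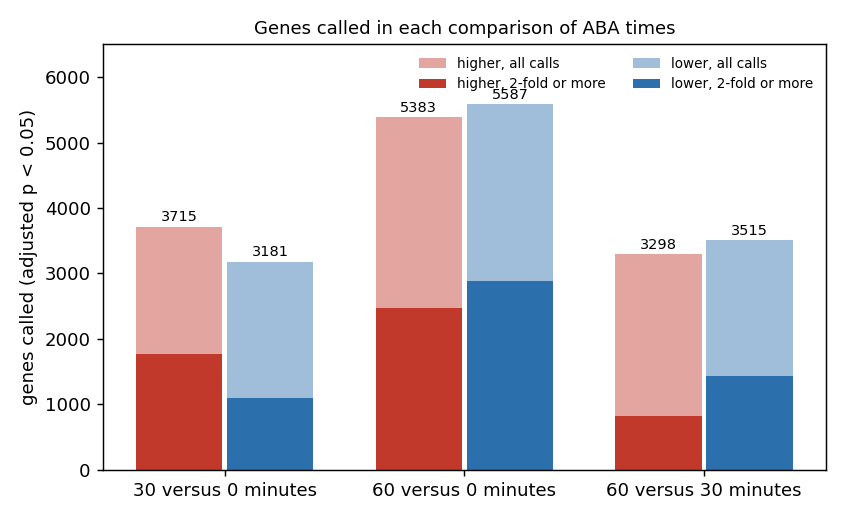
Number of genes called higher or lower (vertical axis, genes at an adjusted p below 0.05) in each of the 3 comparisons (horizontal axis); pale bars are all calls and full bars those with a fitted change of at least 2-fold. At 60 versus 0 minutes 5383 genes were higher and 5587 lower, against 3715 and 3181 at 30 versus 0 minutes.

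The highest fitted fold changes at 60 minutes belonged to genes without a single read at 0 minutes. A fitted fold against 0 counts depends on the method and does not rank how strongly genes rose. For Pp3c23_8960 the fitted log2 fold change at 60 minutes was 12.87 in edgeR and 11.08 in limma-voom. Pp3c23_8960 had 0 counts in both 0 minute libraries, 17.5 ± 0.51 CPM at 30 minutes and 56.7 ± 19.7 CPM at 60 minutes (SD, n = 2), at least 115-fold and 371-fold higher than the floor of 3 counts per library. Pp3c21_2830 likewise went from 0 counts to 11.5 ± 2.50 CPM at 30 minutes and 34.4 ± 6.4 CPM at 60 minutes (SD, n = 2), at least 74.9-fold and 225-fold higher. They had adjusted p of 1.51e-08 and 9.8e-09 at 60 minutes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In all, 41 genes with 0 counts in both 0 minute libraries were called higher at 60 minutes, and 40 of them were already called at 30 minutes. Of the 41, 24 lay at least 10-fold and 6 at least 100-fold above the floor; their median was 2.61 CPM at 60 minutes. The number of such genes was 84 without the expression filter and 10 with the stricter one, and 84 or 63 when replicate 1 or 2 at 0 minutes was left out and the other library alone had to be at 0.

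Among genes that fell, Pp3c17_15630 went from 6.76 ± 1.31 CPM at 0 minutes to 0.86 ± 0.02 at 30 minutes and 0.04 ± 0.05 at 60 minutes (SD, n = 2). A single read remained over both 60 minute libraries, so the 60 minute level was 188-fold lower with an exact 95% counting interval from 33.4 to 7438. Pp3c12_20420 fell from 17.4 ± 2.01 CPM to 1.31 CPM at 30 minutes and 0.18 ± 0.05 CPM at 60 minutes (SD, n = 2), 97.1-fold lower with an interval from 41.4 to 299.9. Their log2 fold changes at 60 minutes were -7.28 (SE 0.51) and -6.55 (SE 0.29), with adjusted p of 2.67e-07 and 4.95e-09 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. For Pp3c17_15630 the value was -6.39 without replicate 1 at 60 minutes and -9.83 without replicate 2, which held its single read. The SEs of both genes, derived from F, were narrower than their counting intervals imply. They understate the uncertainty of folds that rest on so few reads. At 60 minutes 18 called genes had 0 counts in both libraries, with a median of 1.01 CPM at 0 minutes, and 2 of them fell at least 10-fold against the floor. Leaving out replicate 1 or 2 at 60 minutes, so that the other library alone had to be at 0, gave 70 or 67 such genes, and the count was 64 without the filter and 0 with the stricter one.

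Transcripts that rose with ABA came to hold a larger share of the counted mRNA. The 5383 genes called higher at 60 minutes took 25.2% ± 0.03 of gene counts at 0 minutes, 43.3% ± 0.11 at 30 minutes and 54.3% ± 1.34 at 60 minutes (SD, n = 2). The 5587 genes called lower went from 25.8% ± 0.07 to 10.6% ± 0.96. Genes with no call went from 49.0% ± 0.11 to 35.1% ± 0.39. These groups were chosen on the same libraries, so the direction is not independent evidence. With calls made without replicate 1 at 0 minutes the risen group went from 16.4% to 45.5%. Without replicate 1 at 60 minutes it went from 33.4% to 61.2%. The fallen group went from 18.6% to 6.8% without replicate 2 at 0 minutes and from 32.3% to 14.6% without replicate 2 at 60 minutes. These were the lowest and highest shares with 1 library left out of the calls. They still average all libraries of a time, so they are no check on libraries held out. With the calls made on total counts alone, the risen group went from 9.67% to 38.3% and the fallen group from 64.3% to 36.7%. The upper-quartile calls gave 11.1% to 40.0% for the risen group and 54.5% to 29.2% for the fallen group. Cyclic loess offsets gave 17.8% to 47.0% and 40.0% to 19.7%. Requiring an absolute log2 fold change of at least 1 gave 6.72% to 34.5% and 7.5% to 1.77%, and testing against a fold of 1.5 gave 8.66% to 37.1% and 10.0% to 2.76%. The 10 most abundant genes of each library took 5.76% and 5.66% of gene counts at 0 minutes and 4.57% and 4.85% at 60 minutes.

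**Figure D2:**
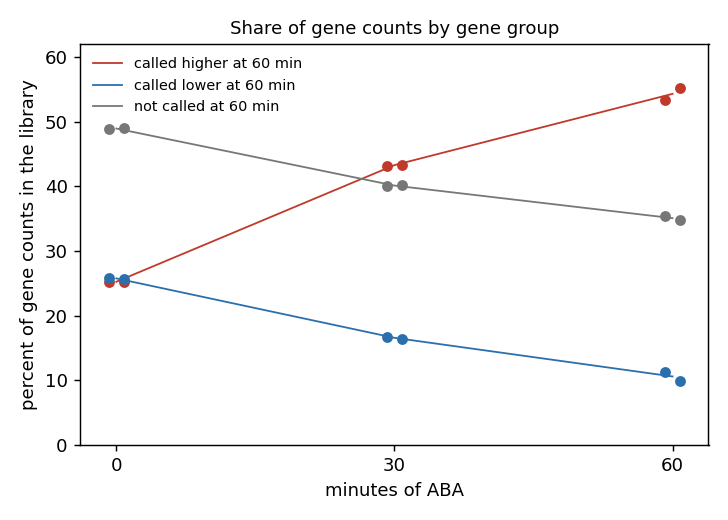
Percent of each library's gene counts (vertical axis) in genes called higher, lower or not called at 60 versus 0 minutes, against minutes of ABA (horizontal axis); points are single libraries and lines join the means. The genes called higher went from 25.2% to 54.3% and the genes called lower from 25.8% to 10.6%.

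The balance of rising and falling genes at 60 minutes was also compared between expression levels. Split by mean log2 CPM at 0 minutes alone, the 6316 highest genes held 2140 that rose and 1593 that fell with TMM, the 6316 next 1644 and 2031, and the 6317 lowest 1599 and 1963. The median log2 fold change of all genes in these groups was 0.08, -0.07 and -0.19. The 0 minute libraries also enter each fold change, so noise in them favours falling genes among the highest and rising genes among the lowest. This split was not repeated with the other scalings. A split by mean log2 CPM over the 6 libraries gave a larger contrast, but 4 of those libraries are treated, so a gene that rose is moved towards the highest group and a gene that fell towards the lowest. Of the highest by that split, 2928 rose and 1003 fell. Of the middle genes 1586 rose and 1889 fell, and of the lowest 869 rose and 2695 fell. The median log2 fold change of all genes was 0.26 among the highest, -0.06 among the middle and -0.50 among the lowest. By the same split, with total counts alone more of the highest genes fell (2723) than rose (1533), against 3895 and 556 among the lowest. The upper-quartile factors gave 2232 falling and 1731 rising among the highest, against 3665 and 622 among the lowest. Cyclic loess offsets, which remove such a trend by construction, gave 2060 rising and 1803 falling among the highest and 1553 rising and 1603 falling among the lowest. The stricter filter left 381 rising and 1514 falling among the lowest. Requiring an absolute log2 fold change of at least 1 left 1216 rising and 273 falling among the highest, and testing against a fold of 1.5 left 1465 and 386, with 1775 falling among the lowest.

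The comparison of 60 with 30 minutes tests whether the response went on, held or turned back. Between these times 3298 genes rose and 3515 fell. Of the genes that had risen by 30 minutes, 1603 rose further, 1642 had no call after 30 minutes and 470 fell back. The genes that rose further had a median log2 fold change of 1.33 at 30 minutes and 2.20 at 60 minutes against 0 minutes; they took 5.9% ± 0.04 of gene counts at 0 minutes and 30.8% ± 1.0 at 60 minutes (SD, n = 2). The 470 genes that fell back had medians of 0.90 and 0.14, and 62 of them ended below their 0 minute level with a call. Of the genes that had fallen by 30 minutes, 1075 fell further (median -0.81, then -1.99), 1851 had no later call and 255 rose back (median -0.80, then -0.07). A further 1440 genes with no call at 30 minutes rose afterwards and 1970 fell; 302 and 244 of these had no call at 60 versus 0 minutes. The shared 30 minute libraries favour calls that turn back. In 20 simulations that kept 6088 genes changed after 30 minutes and gave all others, the genes that turned back included, equal means at 30 and 60 minutes, a mean of 111 genes rose and fell back (highest 131) and a mean of 164 fell and rose back (highest 189). These simulated counts stand against 470 and 255, so part of both groups, and a large part of the genes that fell and rose back, can come from chance or from small early changes that are not called reliably.

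The 4 named genes were chosen for their extreme folds at 60 minutes, which favours a further change after 30 minutes in the same direction, and the test of 60 against 30 minutes uses the same 60 minute libraries. The log2 fold change from 30 to 60 minutes was 1.69 (SE 0.21) for Pp3c23_8960, 1.60 (SE 0.19) for Pp3c21_2830, -4.33 (SE 0.82) for Pp3c17_15630 and -2.82 (SE 0.46) for Pp3c12_20420, with adjusted p between 0.000143 and 0.00197 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. As ratios of counts, the last 2 genes were 24.2-fold (exact 95% counting interval 4 to 988.8) and 7.3-fold (2.9 to 23.8) lower at 60 than at 30 minutes. The value for Pp3c17_15630 was -3.45 without replicate 1 at 60 minutes and -6.89 without replicate 2. Here too the SEs of Pp3c17_15630 and Pp3c12_20420 were narrower than their counting intervals imply and understate the uncertainty. Risen genes were 48.4% of the calls between 30 and 60 minutes with TMM, 35.9% with upper-quartile factors and 16.1% with total counts alone. Without replicate 1 or 2 at 30 minutes, 3604 or 4132 genes were called in place of 6813. Without one of the libraries at 0 or 30 minutes, the genes that rose and fell back numbered 295 and 264 (0 minutes, replicates 1 and 2) or 184 and 224 (30 minutes), and those that fell and rose back 165 and 128 or 92 and 97. Without replicate 1 or 2 at 60 minutes, 440 or 603 genes fell and rose back. Genes that rose further numbered 981 and 982 without replicate 1 or 2 at 30 minutes. Genes that fell further numbered 632 and 656 without replicate 1 or 2 at 0 minutes and 489 and 513 without replicate 1 or 2 at 30 minutes. Genes with no call at 30 minutes that rose afterwards numbered 565 and 676 without replicate 1 or 2 at 30 minutes, and those with no call that fell afterwards 1293 without replicate 1. With total counts alone 894 genes rose further, 2028 fell further, 95 fell and rose back, and of the genes with no call at 30 minutes 291 rose and 4026 fell afterwards. With upper-quartile factors 2063 fell further, 390 fell and rose back and 868 with no call at 30 minutes rose afterwards. DESeq2 gave 275 genes that rose and fell back and 707 that fell further, and 400 genes fell and rose back without the expression filter. With an absolute log2 fold change of at least 1 required in each call, 492 genes rose further, 70 rose and fell back, 260 fell further, 68 fell and rose back, and of the genes with no call at 30 minutes 258 rose and 1103 fell afterwards. Tested against a fold of 1.5, these groups held 557, 67, 233, 28, 235 and 936 genes.

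The changes at 30 and 60 minutes were largely shared. Of the genes that rose by 30 minutes, 3216 (86.6%) were also called higher at 60 minutes, and of those that fell 2635 (82.8%) were also called lower. Opposite calls were made for 81 genes. A further 2148 genes were called higher and 2890 lower at 60 minutes with no call at 30 minutes. Of those, 1010 and 1164 also had no call at 60 versus 30 minutes, so they are not shown to have changed late. Independent lists as long as the calls at 30 and 60 minutes would share 1055 genes that rose and 938 that fell. Unchanged groups with the same shared controls gave a mean of 0.05 shared genes in each direction. That count had to lie near 0, since few genes pass the adjusted threshold when no gene is changed. It does not measure how many shared calls the shared controls add when many genes change. Across genes, the log2 fold changes at the 2 times correlated with r = 0.91, against 0.463 in the simulations of unchanged groups. Their covariance was 1.88, of which the shared 0 minute libraries accounted for 0.0217 in those simulations. The 0 minute group holds 2 libraries and could not be split with 2 libraries in each part, so part of the excess in shared calls can come from the shared controls.

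**Figure D3:**
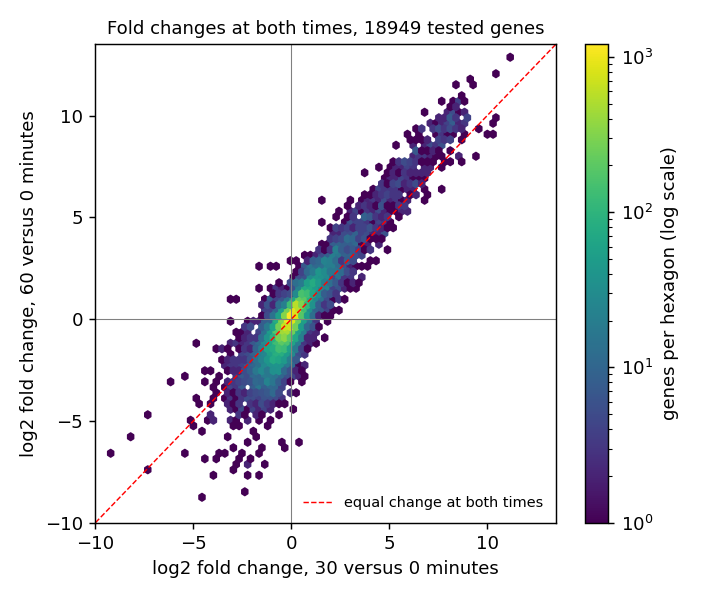
Log2 fold change of each tested gene at 60 versus 0 minutes (vertical axis) against that at 30 versus 0 minutes (horizontal axis); hexagon colour is the number of genes on a log scale and the dashed line marks equal change. Genes lie along the diagonal (r = 0.91).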

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

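The test on reads in no gene was chosen after its values were seen. The difference from 0 minutes was not the same at 30 and 60 minutes for 6813 genes by the test of 60 against 30 minutes, which does not separate ABA from time after an addition, 3298 higher and 3515 lower at 60 minutes. Each of the 4 named genes, chosen for extreme folds at 60 minutes, was among them. Pp3c23_8960 and Pp3c21_2830 differed by 1.69 and 1.60 on the log2 scale, and Pp3c17_15630 and Pp3c12_20420 by -4.33 and -2.82. The last 2 rest on 1 and 5 reads over both 60 minute libraries.

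Reads that fell in no annotated gene, which enter no test above, made up a larger share of every treated library than of either 0 minute library. The share was 1.671% and 1.662% at 0 minutes, 1.987% and 2.036% at 30 minutes, and 2.137% and 1.726% at 60 minutes, with a Wilson 95% interval of 2.028% to 2.043% for the library with the fewest counts (30 minutes, replicate 2), which covers counting error only. The 4 treated libraries averaged 1.97% ± 0.175 (SD, n = 4) against 1.67% ± 0.006 (SD, n = 2); a two-sided exact permutation test of the difference gave p = 0.133, where this design allows no p below 0.067. The libraries at 60 minutes lay further apart (SD 0.291) than those at 30 minutes (SD 0.035).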

How the results depend on the processing

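Dropping 1 gene of each set with nearly the same counts and the cyclic loess offsets were chosen after the data were examined, as were the groups by timing, expression level and 0 counts and the count shares, with all their settings. The 4 counts of called genes stayed within 1.5 times of their reported values under DESeq2, limma-voom, every scaling, both filters, the replicate block, the fit to 4 libraries (not run for the shared count) and those 2. They moved further under the fold thresholds, which accept fewer genes by construction. Requiring an absolute log2 fold change of at least 1 left 2870 genes at 30 versus 0 minutes, 5353 at 60 versus 0 minutes, 2251 at 60 versus 30 minutes and 2540 shared by both times. Testing against a fold of 1.5 with glmTreat left 2830, 5834, 2056 and 2556. Leaving out 1 library gave 4334 to 9172 genes at 30 versus 0 minutes, 8529 to 11888 at 60 versus 0 minutes, 3604 to 8216 at 60 versus 30 minutes and 3947 to 7303 shared, where a group left with 1 library was assumed to vary like the others. The replicate block gave 7589, 11478 and 7499 genes and 6342 shared genes, and ended no call of a named gene. Deviations of same-numbered libraries from their group means correlated with r of -0.053 between 0 and 30 minutes, 0.011 between 0 and 60 minutes and 0.208 between 30 and 60 minutes, and the numbers were not taken as pairs, since the labels do not say that they mark a shared culture or day and only 1 of the 3 correlations exceeded 0.1. No gene called in both a reported comparison and an alternative changed direction, and all 228 alternative values of the named genes kept their direction and their side of the threshold. The named genes were chosen for extreme folds at 60 minutes, so their stability does not speak for other genes. Of calls at 60 versus 0 minutes, 84.5% were kept in the same direction by DESeq2, 80.9% by upper-quartile factors, 76.7% by total counts alone and 78.9% by cyclic loess offsets. Under upper-quartile factors and total counts alone, the loss fell on risen genes only. Of the 5383 genes called higher, these settings kept 3293 and 2830, while all 5587 genes called lower were kept. A gene without a call is not shown to be unchanged: part of the 1.5-fold changes was missed in simulated data, though with only 200 changed genes there the adjusted threshold was stricter than in these comparisons. The gene lists and the upstream element search were not run, because no ID could be tied to a description or a sequence.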

Other observations

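The tests on pairs of genes with nearly the same counts, and the correlation of the 60 minute replicate difference with the early response, were chosen after the pattern was seen; the tests of depth, of expression level and of consecutive IDs were set out before their results. Fewer genes had a count at the later times. With every library thinned to 12450250 gene counts, 21471 and 21357 genes had a count at 0 minutes, 21209 and 21251 at 30 minutes and 20939 and 20816 at 60 minutes. Equal totals do not give unchanged genes equal depth. Genes with no call at 60 minutes held 49.0% of gene counts at 0 minutes and 35.1% at 60 minutes. The lower number of genes can therefore come in part or whole from the changed composition of the counts. Calls at 60 minutes were spread over the 27 ID prefixes from Pp3c1 to Pp3c27. Between 24.8% and 31.9% of the tested genes of a prefix rose and between 26.3% and 33.1% fell, and 0 of the 27 prefixes differed from the rest in either direction after Benjamini-Hochberg adjustment of Fisher's exact tests (1 prefix in each direction had an unadjusted p below 0.05, 0.0223 for genes that rose and 0.0125 for genes that fell).

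Genes with consecutive IDs changed alike at 60 minutes, if IDs follow the order along a chromosome, which the count files do not state. Across 12079 pairs of tested genes 1 place apart, the fold changes correlated with r = 0.173, above all 10000 shuffles within prefixes (highest 0.035; p = 1e-04, the smallest they can give, adjusted p = 0.00016 over 8 correlations; genes are not independent replicates). The correlation was 0.087 at 2 places, also above all shuffles, 0.021 at 5 places (adjusted p = 0.0221), 0.002 at 20 places (adjusted p = 0.44) and 0.019 at 100 places (adjusted p = 0.029). Against reads counted in both genes as the whole cause, r was 0.163 without pairs of nearly equal counts, and without pairs within 1.5 times of each other in every library it was 0.133 at 1 place and 0.076 at 2 places. A response shared by short runs of neighbouring genes is a candidate explanation; partly shared reads and tandem gene copies, which need sequences, stay open.

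Among 10562 genes with a mean count of at least 200, 288 pairs carried counts that differed by at most 2% in each of the 6 libraries, and 95 of these pairs were identical throughout. Redrawing every count from a Poisson distribution left a mean of 16.3 pairs (highest 20 in 20 redraws), so the deposited counts held 17.7 times as many; the redraw adds counting noise of its own, which thins out coincidences too. Coincidence among genes of like level is further argued against by the 218 pairs with consecutive IDs. Reads counted in both genes are a candidate explanation for most pairs. The summary row for ambiguous reads was 0 in every library, but so were the rows for low-quality, unaligned and not uniquely aligned reads. These rows therefore do not show how shared reads were counted. Whether such reads would come through overlapping gene models or through alignment to near-identical copies stays open without the annotation. Keeping 1 gene of each such set changed the number of calls at 60 minutes from 10970 to 10829, and none of the 4 named genes had another gene within 5% of its counts in the 4 libraries where it had at least 10.

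The difference between the replicates at 60 minutes was related to the early response. Across 14580 genes with a mean of at least 5 CPM, the log2 difference of replicate 2 minus replicate 1 at 60 minutes correlated with the 30 versus 0 minute fold change, which uses neither library, with r = 0.211 (95% bootstrap interval over genes 0.197 to 0.225; Spearman 0.271). The median difference was 0.089 for genes that rose by 30 minutes and -0.141 for genes that fell. The bootstrap interval covers the sampling of genes, which are not independent replicates, and not the variation between cultures. No such correlation was computed for the replicates at 0 or 30 minutes, so its usual size between replicates is not known. A trend with expression level as the whole cause was argued against by r = 0.19 after that trend was removed from both measures, while a difference in depth stays open, since thinning both to 16095741 counts took only 8.29% of the deeper replicate and so could not test it (r = 0.211 after). A candidate explanation is that replicate 2 lay further along the response, through timing, uptake or culture state, none of which was tested; the labels give no record of collection.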
